A study of Homo sapiens with 76 samples.

How the data were processed

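Single cells of HEK293, an established human embryonic kidney line, were profiled by 5' selective RNA sequencing with unique molecular identifiers (UMIs), short random tags that let copies of 1 cDNA molecule be counted once. Per the labels' protocols, cells cultured in DMEM with fetal calf serum were captured on a Fluidigm C1 chip with 96 chambers and lysed with 20000 molecules of ERCC spike-in RNA per cell. Polyadenylated RNA was then primed with oligo-dT, the UMI was added at the 5' end by template switching, and the cDNA was amplified by 18 cycles of PCR. The 5' terminal fragments were isolated and sequenced on an Ion Torrent Proton, per the series title. The labels describe 76 cells of 1 line from 1 run, with no treatment and no compared group. They do not say whether the cells came from 1 culture or several, so the group was treated as 1 sample and cells as units of observation, not replicates. No test between groups was made, and every SD and p-value describes the spread among these cells only.

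The deposited values are whole-number counts of UMIs per gene and cell, not normalized, in 1 table of the whole series. The submitters' processing notes name cutadapt 1.2.1, STAR 2.4.0a and the human build hg19 (GRCh37), with no role or order. The tool that counted UMIs, the gene annotation, the treatment of reads that map to several genes and the filter on cells are not given in the sources used here. The protocol in the labels gives an N(4)H(4) tag, which allows 20736 sequences, while the column names carry N6H4, which would allow 331776. A correction for tags used by more than 1 molecule was tried with N(4)H(4), and with N6H4 for UMIs per cell only. The table had 17594 rows. A row called GENE that repeats the column numbers in place of counts was left out; it held 0.197% of the sum of all values. There remained 17513 gene rows and 80 spike-in rows, which were kept apart. Each column was matched to its cell by the run name and the final number, and 0 columns stayed unmatched. The highest correlation between 2 cells was 0.859 and 0 pairs of cells held identical values.

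Totals of gene rows per cell ranged from 7305 to 43392 UMIs. These depths leave genes with few UMIs per cell governed by counting error, and intervals and floors given here cover counting error only. Shares are percent of a cell's endogenous UMIs, averaged over cells. Shares of cells with a UMI have exact Clopper-Pearson 95% intervals, and for a gene seen in 0 of 76 cells the limit of 3 counts (3.95% of cells) is given beside the exact upper bound (4.74%). Both limit cells with a UMI, not cells expressing the gene. To compare genes detected at 1 depth, cells were thinned without replacement to 10940 UMIs, the lowest total among cells with at least 10483 UMIs (the median divided by 2). The 5 cells below that were left out. Spike-in capture is the number of spike-in UMIs as a percent of the 20000 molecules stated, so it and the molecule estimates rest on that nominal number.

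For each gene with a mean of at least 1 UMI per cell, the Pearson dispersion (squared deviation from the count expected from the cell's total, divided by that expectation, summed and divided by the number of cells less 1) was set against 1000 Poisson simulations. A gene was called variable above the 99.9th percentile of its own simulations, with no further correction. Spike-in RNAs were treated in the same way, with spike-in totals as the scale. For gene lists, the mean pairwise Spearman rho between members with a mean of at least 0.5 UMI was placed among 10000 random lists of equal size drawn from the 50 genes outside the list nearest in mean. Lists with fewer than 3 such members gave no value. For the most abundant lists the nearest other genes include less abundant ones. A family of 8 correlations across cells was tested with 100000 two-sided permutations and Benjamini-Hochberg adjustment; the smallest p they can give is 1e-05. Genes outside the cell cycle lists were correlated (Spearman) with the S phase share and with the G2 and M phase share. Their two-sided p came from 100 permutations of the share, pooled over genes, with Benjamini-Hochberg adjustment and a threshold of 0.05.

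Gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes of highest mean share, the 25 variable genes of highest dispersion, the 5 highest and 5 lowest genes past the threshold for each cell cycle share, and the 2 to 4 most abundant members of each list with its number of undetected members. Of the genes this rule takes, 1 is not reported here. Genes that share reads with near-identical copies are uncertain: histones, ribosomal protein genes, EEF1A1, GAPDH, actins, tubulins and HSPA1A with HSPA1B. The alternatives tried were: leaving out the 5 shallow cells, correcting for tag collisions, detection at 2 UMIs, thinning, pooled shares, other scales (spike-in UMIs, or totals without ribosomal protein, mitochondrial and the 10 most abundant genes), other minimum means, noise limits taken from spike-ins, log values, and another correlation. A limit multiplied by the median spike-in dispersion, the N6H4 tag and a regression on the share of long transcripts were added after seeing the data. That last share is the percent of UMIs from protein coding genes with a median transcript over 3000 bases. It covers genes outside the cell cycle, ribosomal protein and mitochondrial lists.

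Gene types and transcript lengths came from GENCODE 29 by symbol, which matched 14215 of the gene rows and 94.4% of the genes tested for variability. That annotation is on GRCh38, another build than the authors', so no coordinates are given. No doublet caller was run, and chambers holding 2 cells cannot be excluded. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated Poisson counts with the real means and totals of 2810 genes. Of genes given an extra coefficient of variation of 0.25, 0.5 and 1, the variability test found 13.4%, 40.3% and 93.9%, and it called 2 of 2610 genes without extra spread. Of genes following a simulated score by 0.15, 0.3 and 0.6 log units per SD, the correlation test found 13.4%, 53.7% and 89.4%, and it called 3 of 2610 unrelated genes. That score was free of counting noise and unrelated genes were drawn independently, so these rates need not hold for the real cell cycle shares.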

Results

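The series profiled 76 single HEK293 cells from 1 run, with UMIs at the 5' ends of transcripts and no compared group. A cell gave a median of 20966 endogenous UMIs (22260 ± 9020, SD, n = 76 cells, range 7305 to 43392). Values after ± are SDs over these 76 cells throughout, and the labels name no replicate cultures. In all, 16918 of the 17513 genes had a UMI in at least 1 cell, 311 genes had one in every cell and 3304 in a single cell. A cell showed a median of 3888.5 genes (2015 to 6016). Thinned to 10940 UMIs, 71 cells showed a median of 2843 genes (2420 to 3577).

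Spike-in RNA, added in equal amount to each chamber, gave a median of 2198.5 UMIs per cell (1390 to 3132), or 10.99% of the molecules stated per cell (6.95% to 15.7%). The coefficient of variation was 15.1% for spike-in UMIs and 40.5% for endogenous UMIs. Scaled by the spike-ins, the median cell held an estimated 187548 RNA molecules open to this assay (73862 to 423865), which assumes equal capture of cellular and spike-in RNA. Endogenous UMIs rose with spike-in UMIs (Pearson r = 0.563, permutation p = 1e-05, adjusted p = 4e-05, and Spearman rho = 0.636, permutation p = 1e-05, adjusted p = 4e-05, both the smallest p the permutations can give). Without the 2 cells farthest from the median spike-in count, r was 0.537. Genes detected rose with endogenous UMIs (r = 0.953 and rho = 0.955, each with permutation p = 1e-05 and adjusted p = 4e-05, and r = 0.949 without the 2 extreme cells). With cells thinned to 10940 UMIs, genes detected still rose with the cells' full UMIs (r = 0.514, rho = 0.584, each with adjusted p = 6e-05, 71 cells). The number in a cell's title was not related to its UMIs past the threshold (r = -0.170, permutation p = 0.143, adjusted p = 0.191, rho = -0.116, permutation p = 0.319, adjusted p = 0.364, and r = -0.107 without 2 cells). With the 5 shallow cells left out, that r was -0.270 with an adjusted p of 0.0363.

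**Figure D1:**
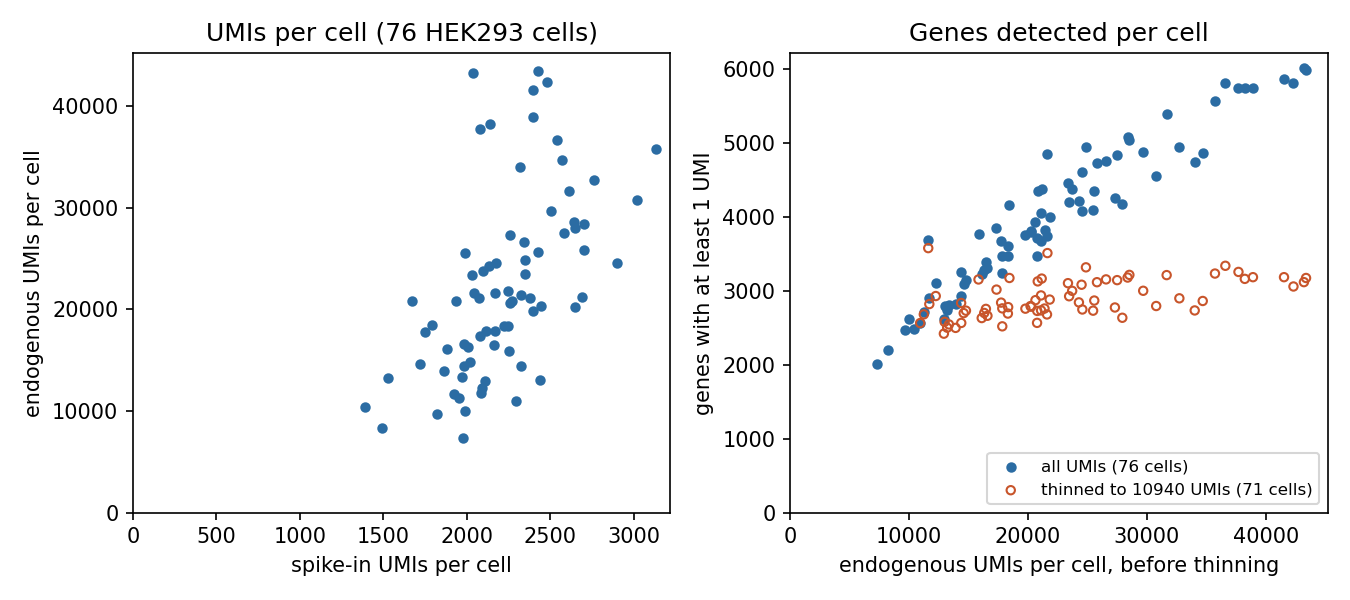
Each point is 1 of 76 cells: endogenous against spike-in UMIs per cell on the left, and genes with at least 1 UMI against endogenous UMIs on the right, before (filled) and after (open) thinning to 10940 UMIs. Genes detected span 2015 to 6016 before thinning and 2420 to 3577 after it.

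Transcripts of the translation apparatus filled the largest part of these profiles among the fixed lists. Genes of cytosolic ribosomal proteins (84 genes) took 29.5% ± 3.20 of a cell's UMIs, from 18.7% to 36.7%. RPLP1 gave 182 ± 64.9 UMIs per cell, RPL37A 171 ± 55.9, RPS27 161 ± 64.2 and RPL31 159 ± 57.4. Translation factors took 1.57% ± 0.186, led by the elongation factor gene EEF1A1 (67.8 ± 33.9 UMIs), NACA (48.9 ± 23.6) and EIF1 (38.8 ± 18.1). The 10 most abundant genes, which together took 8.01% of UMIs, were the mitochondrial ribosomal RNAs MT-RNR2 (1.26% ± 0.567) and MT-RNR1 (0.896% ± 0.431), RPLP1, RPL37A, RPL31, RPS27, RPL39, RPL11, HIST1H4C and MT-ATP8. By gene type, protein coding genes took 88.5% ± 1.09 of UMIs, mitochondrial ribosomal and transfer RNAs 2.54% ± 1.03, pseudogenes 1.63% ± 0.243 and long non-coding RNAs 1.17% ± 0.208. Symbols not matched in GENCODE 29 took 6.04% ± 0.358. Ribosomal protein genes have many processed pseudogenes, so values of single members are uncertain.

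Energy metabolism followed. The 13 messenger RNAs of the mitochondrial genome took 3.58% ± 1.54 (1.24% to 8.68%), led by MT-ATP8 (132 ± 70.6 UMIs), MT-CO2 (103 ± 59.2) and MT-CYB (98.4 ± 54.8). MT-ATP8 lies at the 5' end of a transcript it shares with MT-ATP6 (51.3 ± 27.5 UMIs). MT-ND4L lies likewise at the 5' end of a transcript shared with MT-ND4, but had fewer UMIs per cell (mean 54.4 against 84.8). Whether the place in a shared transcript affects these counts was not tested. Nuclear genes of oxidative phosphorylation took 2.51% ± 0.3003, with COX7C at 54.9 ± 21.99 UMIs and ATP5E at 36.9 ± 15.4. Glycolysis took 1.17% ± 0.249, with GAPDH at 83.0 ± 36.6, LDHB at 41.3 ± 19.3 and ENO1 at 39.7 ± 19.4 UMIs. Cytoskeletal genes took 1.40% ± 0.195, led by the actins ACTG1 (83.3 ± 37.5 UMIs) and ACTB (51.5 ± 26.3) and by TUBA1B (44.1 ± 21.7), all of which have near-identical copies.

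Stress-related lists were less abundant. Chaperone genes took 0.894% ± 0.199, led by HSPD1 (28.2 ± 18.6 UMIs), which encodes the mitochondrial chaperonin, and by HSP90AA1 (24.8 ± 14.0). The list for unfolded protein and amino acid stress took 0.222% ± 0.0590, led by ATF4 (7.72 ± 5.12 UMIs) and the serine synthesis gene PHGDH (6.70 ± 4.61). Hypoxia genes took 0.134% ± 0.0524, mostly the glycolytic LDHA (17.3 ± 11.1 UMIs) and PGK1 (7.89 ± 6.23), and cholesterol synthesis 0.132% ± 0.0439, led by FDFT1 (4.30 ± 3.23) and FDPS (3.71 ± 2.90). Immediate early genes took 0.0889% ± 0.0588, with MYC at 5.76 ± 6.11 and FOS at 4.24 ± 6.07 UMIs. Targets of p53 gave 211 UMIs over all cells. CDKN1A, a cell cycle inhibitor, was seen in 24 of 76 cells (31.6%, exact 95% interval 21.4% to 43.3%) and MDM2 in 20 cells (26.3%, 16.9% to 37.7%). Of 18 interferon response genes 9 were analysed here and gave 206 UMIs, with IFITM1 in 47 cells (61.8%, 49.98% to 72.8%) and IFI6 in 24 cells. Of the translation factor, glycolysis, hypoxia and G2 and M phase lists 1 gene each was not analysed here, and of the cholesterol and p53 lists 2 each.

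Lists of tissue markers were sparse. No cell was named by type. Neuronal genes took 0.0383% ± 0.0291 of UMIs. UCHL1, a neuronal ubiquitin hydrolase, was seen in 70 of 76 cells (4.25 ± 3.66 UMIs), and the neurofilament genes NEFM and NEFL in 49 cells (64.5%, exact 95% interval 52.7% to 75.1%) and 26 cells (34.2%, 23.7% to 45.99%). MAP2 was seen in 0 of 76 cells, which allows a UMI in up to 3.95% of cells by the limit of 3 counts and 4.74% by the exact interval. Of the 20 neuronal genes 9 had no UMI or were not analysed here. Of kidney epithelial genes, the keratins KRT18 and KRT8 were seen in 45 and 19 cells, and the 8 of 23 members analysed here gave 217 UMIs. As a background, the lists these cells should lack gave 18 UMIs for blood and immune genes (HBA1 in 5 cells), 23 for fibroblast and muscle genes (COL1A1 in 8, MYH11 in 3) and 1 for liver genes (APOA1 in 1 cell, FGG in 0). Adrenal genes gave 3 UMIs (CYP17A1 in 2 cells, CYP21A2 in 1). These sums rest on few genes: of the blood list 16 of 20 had no UMI or were not analysed here, of the fibroblast list 8 of 14, of the liver list 11 of 12 and of the adrenal list 10 of 12.

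A histone transcript and mitochondrial RNAs had the highest Pearson dispersions. HIST1H4C, a replication-dependent histone H4 gene, gave 151 ± 120 UMIs per cell and from 0.0464% to 2.14% of a cell's UMIs, with a Pearson dispersion of 90.3 where counting noise alone gives 1. As cDNA was primed with oligo-dT, UMIs of histone, ribosomal RNA and transfer RNA genes count only molecules so primed. How far they stand for a cell's content of these RNAs was not tested. For an equal relative spread the dispersion grows with abundance, so the order of genes is an order by dispersion and not by relative spread. MT-RNR2 had a dispersion of 49.7 and MT-RNR1 43.4. Of the 25 genes of highest dispersion, 15 were mitochondrial. They included the transfer RNA genes MT-TP (32.1), MT-TS2 (19.7) and MT-TF (10.6) and the messenger RNAs MT-ATP8 (19.8), MT-CO2 (18.5), MT-CO3 (17.6), MT-ND4 (17.5), MT-CYB (17.3), MT-ND1 (12.9), MT-ND4L (10.4), MT-ATP6 (10.3), MT-ND5 (8.70) and MT-ND2 (8.27). The long non-coding RNAs MALAT1 (34.8 ± 28.6 UMIs) and XIST (29.7 ± 27.1) had dispersions of 22.6 and 19.8. The ribosomal RNA RNA28S5 followed at 12.3, NEFM at 12.1 and ID2, a repressor of differentiation genes, at 11.1. NEFM gave 2.75 ± 6.01 UMIs with up to 42 in a single cell, and ID2 gave 10.2 ± 11.7 with up to 69. The dispersions of NEFM and ID2 thus rest in part on single cells with high counts. RPS29, RPL39, RPL13 and RPS27 lay at 7.89 to 8.88. These 4 ribosomal protein genes were no longer called with 1 extra squared coefficient of variation, the spike-in median of 0.0621, added for every gene. That value is too large at their abundance: the 8 spike-ins with a mean of at least 80 UMIs had -0.000208 to 0.00823.

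In all, 1804 of 2810 genes tested (64.2%) varied above their Poisson limit, where 2.81 were expected by chance. Spike-in RNAs, which do not differ between cells by design, also exceeded it in 18 of 36 cases, with a median dispersion of 1.53 and a highest of 2.20. A count above Poisson noise therefore includes technical spread. Above the highest spike-in lay 606 genes, and 388 passed a Poisson limit multiplied by the median spike-in dispersion, an alternative chosen after seeing the data. At 10940 UMIs per cell, 618 of 1582 genes were called, at a mean of at least 3 UMIs 909 of 1096, and 874 of 2810 with that extra median variance added to the noise. Against spike-ins, that median is lenient for rare genes: 17 of the 18 spike-ins with a mean of 1 to 6 UMIs exceeded it, and 1714 tested genes had a mean under 3 UMIs. By list, the spike-in based limit was passed by 13 of 13 mitochondrial messenger RNAs, 60 of 80 ribosomal protein genes, 14 of 23 G2 and M phase genes, 12 of 15 cytoskeletal and 7 of 11 glycolytic genes. Over all genes tested 388 of 2810 (13.8%) passed it, and 4 of 24 S phase genes were near that share. It was passed by 8 of 29 oxidative phosphorylation genes, 5 of 17 translation factors, 6 of 18 chaperones and 1 of 12 genes for unfolded protein and amino acid stress. Dispersion grows with abundance, so these counts do not compare relative spread between lists of unlike abundance.

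**Figure D2:**
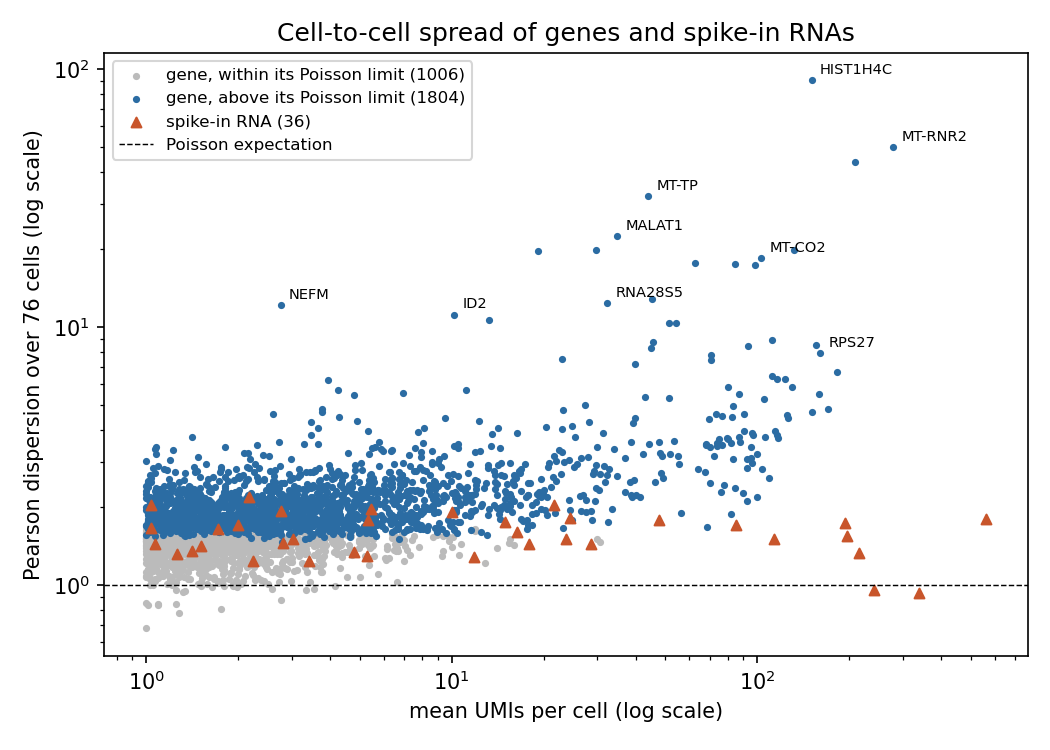
Pearson dispersion over 76 cells against mean UMIs per cell, both on log axes, for 2810 genes (dots; blue above the gene's own Poisson limit) and 36 spike-in RNAs (triangles). HIST1H4C lies highest at 90.3, and the spike-ins lie at or below 2.20.

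Cell division genes varied together from cell to cell. The S phase list took 0.432% ± 0.142 of UMIs (0.155% to 0.852%), with RPA2 at 11.9 ± 7.95, GMNN at 9.43 ± 5.63 and the helicase subunit gene MCM7 at 8.76 ± 6.63 UMIs. Its members had a mean pairwise rho of 0.157, above all 10000 matched random lists. For this and all other lists, the random lists were matched on mean UMIs and not on transcript length. Co-variation was not repeated with the share of long transcripts regressed out. The G2 and M phase list took 0.429% ± 0.195 (0.173% to 1.31%), led by KPNA2 (8.07 ± 7.23 UMIs), CDK1 (7.91 ± 6.68), the mitotic kinase, and CKS2 (7.75 ± 6.10), with a mean rho of 0.147, again above all random lists. Across cells the S phase share fell as the G2 and M phase share rose (r = -0.309, permutation p = 0.00663, adjusted p = 0.0133, rho = -0.258, permutation p = 0.0254, adjusted p = 0.0407), and r was -0.331 without the 2 extreme cells. With cells thinned to 10940 UMIs r was -0.337 (adjusted p = 0.00774), while rho was -0.239 and missed the threshold (adjusted p = 0.0663). All 30 S phase genes were detected, as were the 35 G2 and M phase genes analysed here.

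Other lists varied together too. Mitochondrial messenger RNAs had a mean pairwise rho of 0.729, ribosomal protein genes 0.190, immediate early genes 0.172, glycolysis 0.153 and chaperones 0.135, all above every random list. Replication-dependent histones (0.142, percentile 99.98 among random lists), oxidative phosphorylation (0.0594, percentile 99.95) and unfolded protein and amino acid stress (0.0586, percentile 98.1) also passed the 95th percentile. The last did not with spike-in scaling (percentile 62.6) or a lower minimum mean (percentile 87.3). Hypoxia (0.0664, percentile 92.2), translation factors (0.0175, percentile 65.6), cholesterol synthesis (0.0242, percentile 57.7), cytoskeleton (0.00867, percentile 57.4) and neuronal genes (0.0233, percentile 53.1) lay below it. Hypoxia passed at a lower minimum mean (percentile 98.3). The p53, interferon, kidney, adrenal, blood, fibroblast and liver lists had too few abundant members.

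**Figure D3:**
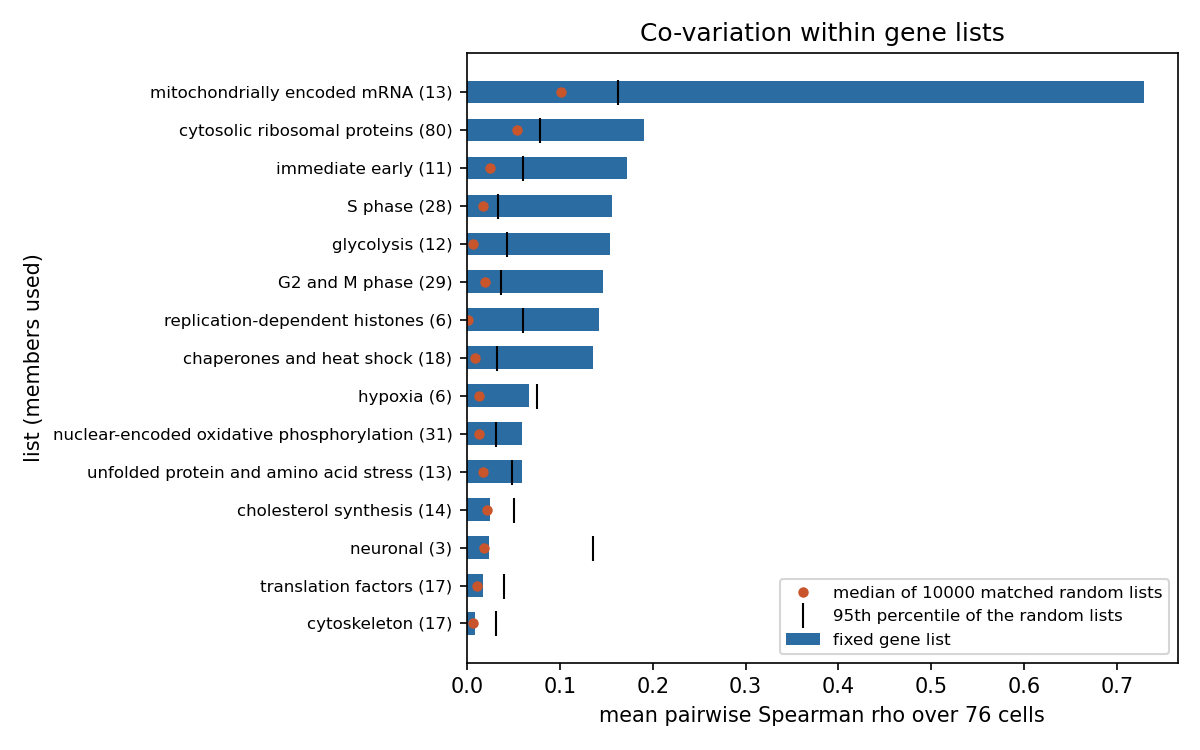
Mean pairwise Spearman rho over 76 cells within each gene list (bars, members used in brackets), with the median (dot) and 95th percentile (tick) of 10000 random lists matched on mean expression. Mitochondrial messenger RNAs reach 0.729, while hypoxia, cholesterol synthesis, neuronal, translation factor and cytoskeletal genes stay below their ticks.

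USP1, MSH6 and the chaperone genes HSP90AA1 and HSPD1 rose with the S phase share. Of 80 ribosomal protein genes, 13 fell with it when scaled by cell totals, although RPL23A, RPS29, RPS27 and RPLP0 turned to positive correlations with spike-in scaling, under which a cell's RNA content enters both measures and all called genes were higher. Of 2763 genes outside the cell cycle lists, 57 passed the adjusted threshold, 34 higher and 23 lower. The highest were USP1, a deubiquitinase of DNA repair (rho = 0.509, permutation-based adjusted p = 0.00833), COPRS (0.464, adjusted p = 0.012), the mismatch repair gene MSH6 (0.464), HSP90AA1 (0.451) and HSPD1 (0.449, adjusted p = 0.0139). The lowest were TMEM256 (-0.511, adjusted p = 0.00833), RPL23A (-0.493), RPS29 (-0.487), RPS27 (-0.484) and RPLP0 (-0.484). Adjusted over the list alone, 28 ribosomal protein genes were lower. Of 18 chaperone genes 2 were higher, and 5 adjusted over the list alone. Of 10 cholesterol synthesis genes 1 was higher under both adjustments. These calls depended on the scale. With totals free of abundant genes 5 genes passed (2 higher, 3 lower, of which 1 a ribosomal protein gene). With cells thinned 8 of 1549 passed (2 higher, 6 lower), and 222 had an unadjusted permutation p under 0.05, against 427 of 2763 unthinned. With spike-in scaling 1943 passed (all higher), and with the share of long transcripts regressed out, added after seeing the data, 1. That share itself fell as the ribosomal protein share rose (rho = -0.749, permutation p = 1e-05, adjusted p = 3.75e-05, r = -0.810, permutation p = 1e-05, adjusted p = 2.5e-05, over 15 relations, and r = -0.745 without 2 cells).

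Of 2763 genes, 10 followed the G2 and M phase share past the threshold, 7 higher and 3 lower. This is fewer than for the S phase share, but the order of these counts turned with totals free of abundant genes (14 against 5) and with the share of long transcripts regressed out (11 against 1). At an unadjusted permutation p under 0.05 it turned only with the latter (331 against 235) and not with the former (319 against 346). The highest were PTBP1, a splicing regulator (rho = 0.523, permutation-based adjusted p = 0.015), DEPDC1 (0.517), HES1, a transcriptional repressor of the Notch pathway (0.492), CALM2, which encodes calmodulin (0.473), and the nuclear pore gene NUP37 (0.466). The 3 lower ones were RPL8 (-0.481), NHP2 (-0.459) and RPLP2 (-0.424, adjusted p = 0.049), all of which turned to positive correlations with spike-in scaling, as all genes called under it were higher. Adjusted over the list alone, 9 ribosomal protein genes were lower against 2 over all genes, and 4 cytoskeletal genes were higher and 2 lower against 0. With cells thinned to 10940 UMIs 0 of 1549 genes passed (147 at an unadjusted p under 0.05), with spike-in scaling 1888 passed (all higher), at a mean of at least 3 UMIs 22 (7 higher, 15 lower), and by Pearson correlation of log values 16 (11 higher, 5 lower).

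Ribosomal protein share fell as cells held more UMIs (r = -0.391, permutation p = 0.00051, adjusted p = 0.00136, rho = -0.447, permutation p = 8e-05, adjusted p = 0.000213, and r = -0.387 without the 2 extreme cells). Given the share of long transcripts, added after seeing the data, that r was -0.207 with an adjusted p of 0.117. The share of long transcripts itself rose with UMIs (rho = 0.432, permutation p = 0.00011, adjusted p = 0.000275, in a separate family of 15 relations). It is thus tied to both measures, so the drop cannot be credited to transcript length. The G2 and M phase share rose with UMIs (r = 0.251, permutation p = 0.0288, adjusted p = 0.0461, rho = 0.351, permutation p = 0.00215, adjusted p = 0.0043). Without the 2 extreme cells r was 0.181 with an adjusted p of 0.161, so the linear relation rests in part on those cells, while rho was 0.307 with an adjusted p of 0.016. Without the 5 shallow cells r was 0.183, and with cells thinned it was 0.170, with adjusted p of 0.170 and 0.187. It passed on a log scale (r = 0.336, adjusted p = 0.00582) and given the share of long transcripts (r = 0.297, adjusted p = 0.0191). The S phase share (r = 0.155, permutation p = 0.181, adjusted p = 0.207, rho = 0.145, permutation p = 0.208, adjusted p = 0.277, r = 0.225 without 2 cells) and the mitochondrial share (r = -0.00645, permutation p = 0.955, adjusted p = 0.955, rho = 0.0702, permutation p = 0.545, adjusted p = 0.545, r = -0.0114 without 2 cells) showed no relation with UMIs past the threshold. These are 8 relations of 1 family, and all cells came from 1 run, so none could be repeated within batches.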

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

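Before the data were examined, alternatives were fixed for every planned result, but not for the relations under other observations. The alternatives on long transcripts, the N6H4 tag and the multiplied spike-in limit were chosen after seeing the data. The 22 list shares stayed within 1 SD over cells when shallow cells were left out, tags were corrected or UMIs were pooled. UMIs per cell and spike-in capture did so without shallow cells and with tags corrected. These changes could hardly move a mean or median by 1 SD over cells, so this result is no test of robustness. Genes detected moved from 3888.5 to 2151 at 2 UMIs and 2843 after thinning, which lowers the counts by construction. Variable genes moved from 1804 to 874 with extra spike-in variance, 388 with the multiplied limit, 909 at a mean of at least 3 UMIs (1096 genes tested) and 618 after thinning (1582 tested). Without shallow cells and with totals free of abundant genes, all 15 list co-variations kept their side of the 95th percentile. Unfolded protein and amino acid stress lost it with spike-in scaling (0.192) and at a lower minimum mean (0.0379), and hypoxia gained it there (0.0684).

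Genes following the S phase share numbered 57, against 5 with totals free of abundant genes, 1943 with spike-in scaling, 8 after thinning (1549 tested) and 1 with long transcripts regressed out. Those following the G2 and M phase share numbered 10, against 1888 with spike-in scaling, 22 at a mean of at least 3 UMIs, 0 after thinning and 16 by Pearson correlation of log values. Spike-in scaling leaves each cell's RNA content in both the gene and the share, so most genes then rise together. With it the correlations turned positive for RPLP0 (0.367), RPS27 (0.401), RPS29 (0.252) and RPL23A (0.453) with the S phase share, and for RPLP2 (0.452), NHP2 (0.206) and RPL8 (0.244) with the G2 and M phase share. The relation of G2 and M phase share to UMIs missed the threshold without shallow cells (0.183), after thinning (0.170) and without 2 extreme cells (0.181). That of ribosomal protein share missed it given long transcripts (-0.207), and title number passed it without shallow cells (-0.270). Of the 25 named dispersions, 4 fell under their limit with extra spike-in variance (RPS29, RPL39, RPL13 and RPS27), a flat median too large for abundant genes. None did under the other settings, where NEFM was not tested at a mean of at least 3 UMIs. Of the named correlations, 11 missed the threshold after thinning and 3 kept it, 10 missed it and 8 kept it with long transcripts regressed out, and 8 missed it and 10 kept it with totals free of abundant genes, all with their sign kept. Where no reason is given, the cause was not tested. Thinning gave no value for spike-in UMIs and title number. At the depth of these cells, the simulations found 40.3% of genes with an added coefficient of variation of 0.5.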

Other observations

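The relations below were looked for after the data were seen, as a family of 15 with permutation p-values. They were chosen from a wider look at lists and genes that was not counted, so their adjusted p-values are too small, and they describe these 76 cells only. Where the mitochondrial messenger RNA share was higher, the immediate early share was higher too (Pearson r = 0.337, permutation p = 0.00286, adjusted p = 0.00613, Spearman rho = 0.426, permutation p = 0.00016, adjusted p = 0.000343, and r = 0.389 without the 2 extreme cells). The nuclear genes of oxidative phosphorylation showed no such relation past the threshold (r = 0.0155, permutation p = 0.892, adjusted p = 0.927, rho = 0.0685, permutation p = 0.557, adjusted p = 0.597, r = 0.0798 without 2 cells), though both lists serve 1 pathway. The chaperone share rose with the S phase share (r = 0.570, permutation p = 1e-05, adjusted p = 2.5e-05, rho = 0.527, permutation p = 1e-05, adjusted p = 3.75e-05, r = 0.526 without 2 cells). The S phase share also followed the share of long transcripts (rho = 0.414), and the chaperone relation was not tested given that share. With that share regressed out, 0 genes were called higher with the S phase share, so HSP90AA1 and HSPD1 lost their calls.

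Of the tests that follow, those on HIST1H4C and on damaged cells were chosen after their results were seen. The labels name no groups of cells, so no biological explanation was tested for any of the 3 patterns. Intervals are 95% bootstrap intervals over cells.

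HIST1H4C ranged from 0.0464% to 2.14% of a cell's UMIs. Sequencing depth as the source would tie the share to a cell's UMIs, but a quadratic trend on ranked UMIs accounted for 4.21% of its rank variance (0.340% to 18.8%). The summed share of 26 H1, H2A and H2B genes, 480 UMIs in all, rose with it (rho = 0.621, permutation p = 1e-05, adjusted p = 3.75e-05, r = 0.590, permutation p = 1e-05, adjusted p = 2.5e-05, r = 0.598 without 2 cells). Reads shared between H4 copies were not tested, since the other 7 H4 genes held 26 UMIs in all, and from which copies the UMIs came stays open. HIST1H4C did not follow the S phase list past the threshold (rho = -0.182, permutation p = 0.114, adjusted p = 0.149, r = -0.236, permutation p = 0.0408, adjusted p = 0.0612, r = -0.234 without 2 cells). Nor did it follow the G2 and M phase list (rho = 0.129, permutation p = 0.263, adjusted p = 0.303, r = 0.0107, permutation p = 0.927, adjusted p = 0.927, r = 0.0164 without 2 cells). No cell was assigned to a phase, so these values do not show that HIST1H4C is unrelated to DNA replication.

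The mitochondrial messenger RNA share fell where the glycolysis share rose (r = -0.659, permutation p = 1e-05, adjusted p = 2.5e-05, rho = -0.700, permutation p = 1e-05, adjusted p = 3.75e-05, r = -0.685 without 2 cells). Shares must sum to a whole, but with mitochondrial UMIs taken out of the total rho was still -0.647 (-0.779 to -0.456). Given the share of long transcripts it was -0.718 (-0.827 to -0.562). That share had no relation with the mitochondrial share past the threshold (rho = 0.00834, permutation p = 0.943, adjusted p = 0.943), so regressing it out could hardly change the value. It also leaves out mitochondrial genes, so an effect of transcript length was not excluded. Loss of cytoplasmic RNA from damaged cells would leave few endogenous UMIs per spike-in UMI where the mitochondrial share is high, and that rho was 0.0925 (-0.138 to 0.317). The value without mitochondrial UMIs argues against closure as the whole source of the pattern. The rho for damage gave no sign of such loss over all cells, but this test was chosen after its result was seen. Endogenous UMIs per spike-in UMI also vary with a cell's RNA content, so damage in some of the cells cannot be excluded. Doublets and uneven capture were not tested.

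The S phase share rose where the ribosomal protein share fell (r = -0.517, permutation p = 1e-05, adjusted p = 2.5e-05, rho = -0.475, permutation p = 3e-05, adjusted p = 9e-05, r = -0.409 without 2 cells). Given endogenous UMIs rho was -0.464 (-0.644 to -0.260). The S phase share had no relation with UMIs past the threshold (rho = 0.145, permutation p = 0.208, adjusted p = 0.277), so regressing UMIs out could hardly change the value. That weak relation gave no sign that the S phase share rises or falls with depth, and other effects of depth were not tested. Closure of shares and transcript length could each account for part of the pattern and cannot be told apart from a cell cycle effect. With ribosomal protein UMIs taken out of the total rho was -0.374 (-0.577 to -0.160). Given the share of long transcripts it was -0.274 (-0.488 to -0.0518), and both values lay between the bounds set for either outcome. With totals free of abundant genes the lower ribosomal protein genes fell from 13 to 1. Calls of all genes fell from 57 to 5 there, so that drop was not particular to ribosomal protein genes. Genes at an unadjusted permutation p under 0.05 moved from 427 to 346. The share of long transcripts itself followed the ribosomal protein share (rho = -0.749, permutation p = 1e-05, adjusted p = 3.75e-05, r = -0.810, permutation p = 1e-05, adjusted p = 2.5e-05, r = -0.745 without 2 cells) and the S phase share (rho = 0.414, permutation p = 0.0002, adjusted p = 0.000375, r = 0.470, permutation p = 1e-05, adjusted p = 2.5e-05, r = 0.386 without 2 cells). Across 2606 genes, which are not independent, longer transcripts had higher correlations with the S phase share (rho = 0.359).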
